A study of Homo sapiens with 18 samples.

How the data were processed

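The data came from HEK293 cells co-transfected with a FLAG-AGO2 or control FLAG plasmid and 100 nM of a negative control RNA oligo, a miR-668 mimic or a miR-489 mimic. RNA was taken 48 h later from the lysate (total RNA) and from the anti-FLAG pull-down (RISC RNA). The labels do not say which plasmid each library received, and none is labelled as a pull-down from cells without FLAG-AGO2. The lowest AGO2 value of any library was 8600 FPKM, but no level without the FLAG-AGO2 plasmid was available for comparison. The labels call the libraries of each of the 6 groups repeats I, II and III and do not say that they came from separate cultures, so all p-values measure the spread between these 18 libraries. The values were FPKM per locus, computed by the authors with Cufflinks 2.0.2 on hg19 per the submitters' processing notes, and the deposited table held 49115 loci and 18 value columns. Every value column was matched to a library. The table held no column that marks failed estimates, so a value of exactly 0 may be either an absent transcript or a failed estimate and is described as listed at 0, and no fold is given against a group listed at 0 throughout. Read counts were not used, and the absolute sequencing depth of the libraries was not known. Depth relative to the first control total RNA library was estimated from the smallest values above 0 and was 0.398 to 1.93. The median standard error of a contrast was 0.163 for comparisons of 2 groups and 0.231 for recruitment.

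The groups, comparisons, gene lists and alternative settings were fixed, except where stated, before the data were examined. Loci with FPKM of at least 1 in at least 3 libraries were kept, which left 15355 loci. Of these, 137 were small RNA loci, 2822 had no gene symbol and 794 joined several symbols in 1 locus. Values were taken as log2(FPKM + 1) and fitted with limma 3.58.1 (R 4.3.3) with 6 group means and an intensity trend. In all, 10 contrasts were tested. RISC enrichment is RISC RNA minus total RNA within 1 treatment (3 comparisons). Recruitment is the RISC enrichment with a mimic minus the RISC enrichment with the control oligo (a pair of comparisons), and recruitment with miR-668 was also compared directly with recruitment with miR-489. RISC RNA and total RNA with each mimic were compared with the same fraction with the control oligo (4 comparisons). P-values were adjusted with the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Confidence intervals are 95% intervals of the contrast, not adjusted for the number of loci. All comparisons with the control oligo share its 3 libraries per fraction.

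Genes are named by a fixed rule. MTFP1, PARP1 and AGO2, which carries its older symbol EIF2C2 in the table, are given in each comparison where they bear on the question. The 10 highest and 10 lowest contrasts past the threshold are given for recruitment and total RNA with each mimic and for RISC enrichment with the control oligo, and 5 and 5 for the other comparisons. Loci without a symbol and microRNA, snoRNA, snRNA and rRNA loci were left out of these. Of each gene list named, up to 4 members with the largest change among those with mean FPKM of at least 5 are given. Some genes that meet this rule are not reported here. MTFP1 and PARP1 are the genes the study followed up, and they were chosen with knowledge of these libraries, so their values are not independent of that choice.

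A set of 22 gene lists was written from general knowledge: the study targets, AGO and RISC factors, mRNA deadenylation and decay, let-7 targets, miR-17 family targets, mitochondrial dynamics, PARP and base excision repair, apoptosis, hypoxia response, p53 targets, interferon response, immediate early and stress genes, ER chaperones, cell cycle, cytosolic ribosomal proteins, mitochondrially encoded mRNAs, nuclear retained RNAs, replication dependent histones, haematopoietic markers, fibroblast and endothelial markers, epithelial markers and neuronal markers. The study targets and the fibroblast and endothelial markers had only 2 loci each and were not put through the set test. Lists were tested with camera of limma, with a preset correlation between genes of 0.01 and again with an estimated correlation, and p-values were adjusted with the Benjamini-Hochberg method over the lists of a comparison. List members were also adjusted over the list alone.

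Seed matches were counted in the 3' UTR and the coding sequence of GENCODE v29 (GRCh38). The loci of the table are on GRCh37, and the 2 builds were joined by gene symbol only. Site coordinates are given on GRCh38 and locus coordinates on GRCh37. The labels do not state the microRNA arm, and the 3p arms were taken. The sites were the 7-base words GAGTGAC and AGTGACA and the 8-base GAGTGACA for miR-668-3p, GATGTCA, ATGTCAA and GATGTCAA for miR-489-3p, and GGTTGTG, GTTGTGA and GGTTGTGA for the control word. The control word is the seed match of cel-miR-67-3p, on which a common mimic control is based, and the labels do not name the sequence of the control oligo. Genes with a site were compared by camera with genes without one, matched on mean expression and 3' UTR length in 10 bins per covariate, and 100 draws of matched genes were made with random seed 1. The p-values of these 20 seed tests were adjusted together. In all, 11088 genes (72.2% of the loci) were used. The symbol matching was improved once after a first result was seen, which moved 1 seed test across the threshold. Word ranks over all 7-base words of the 3' UTR and Fisher tests of site shares (72 tests, adjusted together) were added after the seed tests were seen.

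The fit was tried on simulated changes. In total RNA with miR-668, 44 of 100 planted 1.5-fold changes and 90 of 100 planted 2-fold changes were found, with 10 false calls. For recruitment of miR-668, 18 and 69 of 100 were found, with 4 false calls. A planted seed difference of -0.1 came back as -0.0987. The repeats were not treated as pairs: 17 of 45 pairs of libraries with the same number had a correlation over 0.1 after group means were removed (median 0.052), and 9 of 18 libraries were closest to a library of their own number. All 3 pairs of control total and control RISC RNA exceeded that value (0.214, 0.307 and 0.131), and interferon response genes and AGO2 differed by repeat number, so a fit with the repeat number as a block was made as well. The fit used for the report and the splits of the libraries leave the repeat number out. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the word counts and the figures. Values are given as mean ± SD of FPKM (n = 3), contrasts as log2 with the standard error (SE).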

Results

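AGO2, the Argonaute protein through which the pull-down was made and which was also supplied on the plasmid, was among the most abundant transcripts: its FPKM was 8600 to 18320 in the 9 total RNA libraries and 51820 to 97960 in the 9 RISC RNA libraries. MTFP1, which encodes a fission factor of the inner mitochondrial membrane, was measured in 1 locus joined with SEC14L2 and had similar FPKM in 5 of the 6 groups and a higher one in RISC RNA with miR-668. PARP1, which encodes the DNA damage sensor poly(ADP-ribose) polymerase 1, had FPKM of 163.8 ± 12.7 in total RNA with the control oligo and 188.5 ± 14.4 with miR-489 (SD, n = 3). The 18 libraries came from 6 groups of 3. FPKM totals were 638200 to 1312300, and 13418 to 13860 loci per library had FPKM of at least 1. Relative depth against the first control total RNA library, computed from the smallest values, was 0.950 to 1.93 in total RNA and 0.398 to 1.48 in RISC RNA. Correlations were 0.947 to 0.970 within groups and 0.895 to 0.934 between RISC and total RNA, and the first component, which separated the fractions, held 39.5% of the variance. The repeats are not stated to be separate cultures, so the p-values below measure the spread between these libraries.

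**Figure D1:**
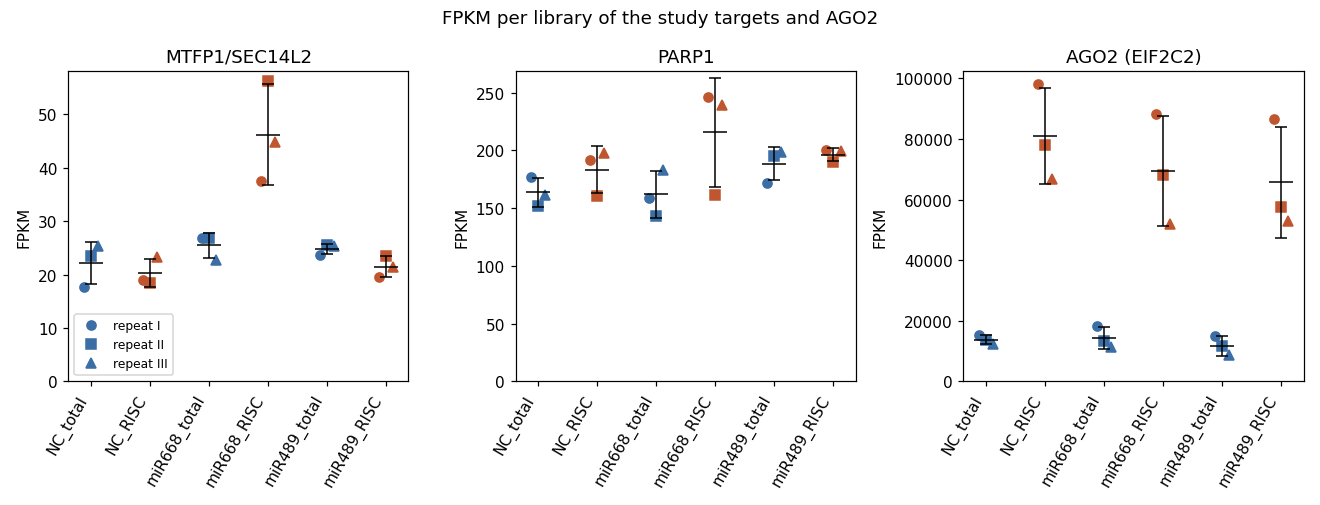
FPKM of MTFP1/SEC14L2, PARP1 and AGO2 in the 18 libraries. Points are the repeats and bars are mean ± SD (n = 3).

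In cells with the control oligo, the transcripts most enriched in RISC RNA over total RNA were mitochondrial. MT-CYB, which encodes cytochrome b of complex III, and MT-ND6, which encodes a subunit of complex I, led the list together with the nuclear pseudogenes MTND2P28 and MTND1P23. ZYX, which encodes the focal adhesion protein zyxin, ZNF385A, a zinc finger protein that binds RNA, GRINA, a Golgi and ER membrane protein linked to calcium control, FOSL1, an AP-1 transcription factor subunit, and the pseudogene MTND6P4 were enriched as well. Among the most depleted were GOLGA8A/GOLGA8B, a pair of golgin copies, a locus of the Rab11 effector RAB11FIP3, the nuclease partner EME2 and the antisense transcripts ASMTL-AS1 and PPP2R3B-AS1. The symbol RAB11FIP3 also has a more abundant locus, whose values are not given here. AGO2 itself rose 2.55 in log2 (SE 0.266, limma with Benjamini-Hochberg adjustment, adjusted p = 1.51e-06), from 13730 ± 1520 to 80950 ± 15700 FPKM (SD, n = 3).

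MT-CYB stood at 1420 to 1585 FPKM in total RNA and 17790 to 20680 in RISC RNA, a contrast of 3.65 (SE 0.126, limma with Benjamini-Hochberg adjustment, adjusted p = 1.12e-11), and MT-ND6 rose 3.87 (adjusted p = 3.64e-11). MTND2P28 rose 4.04, MTND1P23 3.17 and MTND6P4 2.78, and these pseudogenes share reads with the mitochondrial genes they copy. MTND6P3 was listed at 0 in all 3 total RNA libraries and at 93030, 124800 and 0.00518 FPKM in RISC RNA, so no fold is given. ZYX rose 2.94 (SE 0.0832), ZNF385A 2.93, GRINA 2.84 and FOSL1 2.70 (limma with Benjamini-Hochberg adjustment, adjusted p from 1.02e-12 to 1.93e-08). GOLGA8A/GOLGA8B (-2.91, adjusted p = 9.4e-11), RAB11FIP3 (-2.66), ASMTL-AS1 (-2.62), MST1 (-2.53), PPP2R3B-AS1 (-2.52), EME2 (-2.50), MXRA8 (-2.39), NCRNA00342 (-2.20) and CCDC144A (-2.20) fell (limma with Benjamini-Hochberg adjustment). NCRNA00106 was listed at 0 in all 3 control RISC RNA libraries, and the strand of the antisense loci is not stated, so their values are uncertain. Mean FPKM in control RISC RNA was under 1 for RAB11FIP3 (0.459), ASMTL-AS1 (0.566), NCRNA00342 (0.570) and CCDC144A (0.852). The size and order of these contrasts therefore depend on the 1 FPKM added before log2. PARP1 did not differ between the fractions (0.16, adjusted p = 0.384), and neither did MTFP1/SEC14L2 (-0.12, adjusted p = 0.547, both limma with Benjamini-Hochberg adjustment). In total 4138 loci were higher and 2137 lower in RISC RNA of 15355 tested by limma, 65.9% of them higher. The split depended on scaling: median-ratio scaling, which moved the median contrast by -0.167, gave 2667 and 3264 (45% higher). Correction for transcript length and GC content could be made for 11210 loci. It took these from 3710 and 1439 (72.1% higher) to 2465 and 2273 (52%), with a shift of -0.173. The correction also set all libraries to the same mean over these loci, so the changed split cannot be credited to length and GC content alone.

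**Figure D2:**
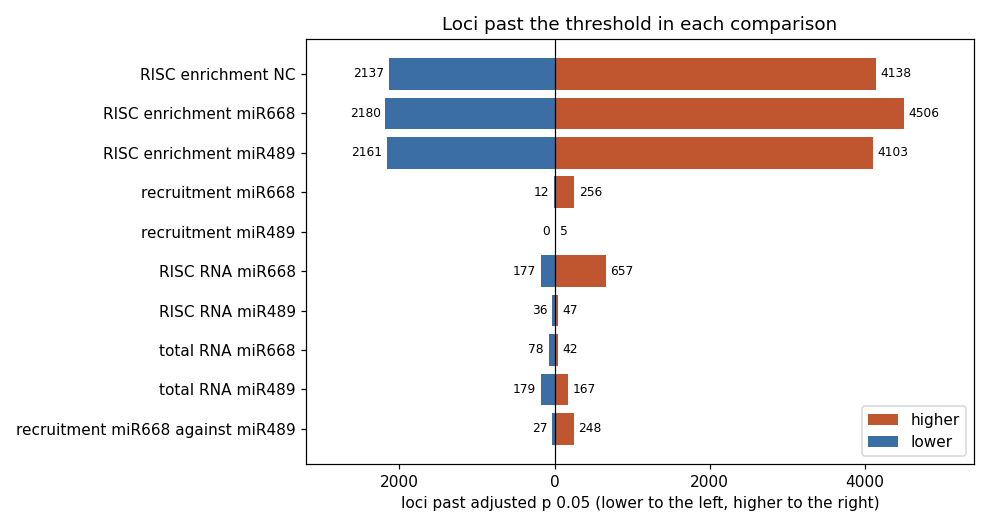
Number of loci higher and lower past the threshold in each of the 10 comparisons. Limma with Benjamini-Hochberg adjustment at 0.05.

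Among the lists of nuclear genes tested by camera, immediate early and stress genes had the highest median in RISC RNA with the control oligo, and ER chaperones the lowest. EGR1, a growth-induced transcription factor (2.24), the heat shock genes HSPA1A (1.86) and HSPA1B (1.80) and the mRNA decay factor ZFP36 (1.74) led the immediate early list. It had 22 higher and 1 lower of 28, 26 and 1 when adjusted over the list alone, median 0.92 (camera with Benjamini-Hochberg adjustment, adjusted p = 2.85e-08, adjusted p = 0.187 with an estimated correlation). The chaperones SDF2L1 (-2.17), HSP90B1 (-2.01), CRELD2 (-1.83) and PDIA4 (-1.66), whose mRNAs are translated at the ER, had 16 lower of 22, 17 when adjusted over the list alone, median -0.81 (camera with Benjamini-Hochberg adjustment, adjusted p = 2.85e-08, adjusted p = 0.218 with an estimated correlation). Cytosolic ribosomal protein genes had 13 higher and 50 lower of 76, 14 and 50 when adjusted over the list alone, median -0.41 (camera with Benjamini-Hochberg adjustment, adjusted p = 3.32e-11, adjusted p = 0.367 with an estimated correlation). Of these RPL39 (-1.62) and RPS28 (-1.31) fell, and such genes share reads with their pseudogenes. Cell cycle genes, with CDC25A (1.69), CDT1 (1.24), PLK1 (1.18) and CCNE1 (1.18), had 27 higher and 2 lower of 34, 28 and 2 when adjusted over the list alone, median 0.41 (camera with Benjamini-Hochberg adjustment, adjusted p = 3.15e-05, adjusted p = 0.187 with an estimated correlation).

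Targets of microRNAs that HEK293 cells make themselves stood higher in RISC RNA. The miR-17 family targets MYLIP (1.67), TXNIP (1.64), SQSTM1 (1.49) and E2F2 (1.28) led 19 higher and 0 lower of 24, 19 and 2 when adjusted over the list alone, median 0.50 (camera with Benjamini-Hochberg adjustment, adjusted p = 6.43e-05, adjusted p = 0.116 with an estimated correlation). Among let-7 targets CDC25A, NR6A1 (1.3), ARID3B (1.28) and PLAGL2 (1.22) led 16 higher and 1 lower of 27, with the same counts when adjusted over the list alone, median 0.41 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0041, adjusted p = 0.278 with an estimated correlation). Transcripts of the decay machinery itself, DCP1B (1.23), EDC3 (1.14), CNOT3 (1.05) and PARN (0.97), had 11 higher and 0 lower of 23 and the same when adjusted over the list alone, median 0.35 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00709, adjusted p = 0.187 with an estimated correlation). The p53 targets BTG2 (1.57), AEN (1.24), PPM1D (1.13) and SESN2 (1.12) had 12 higher and 0 lower of 25 and the same when adjusted over the list alone, median 0.45 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0034, adjusted p = 0.366 with an estimated correlation). The neurofilament genes NEFH (1.75), NEFL (1.33), INA (1.0) and NEFM (0.86) led the neuronal markers, 4 higher of 9, median 0.53 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0298, adjusted p = 0.187 with an estimated correlation). MALAT1, which stays in the nucleus, fell by 0.76 and GAS5 fell by 0.56 while PVT1 rose 0.58. Nuclear retained RNAs had 1 higher and 2 lower of 7, 1 and 3 when adjusted over the list alone, median -0.25 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0358, adjusted p = 0.187 with an estimated correlation). Under median-ratio scaling the medians were 0.30 for miR-17 family targets, 0.21 for let-7 targets, 0.14 for the decay genes, 0.25 for p53 targets and 0.21 for cell cycle genes. Those of nuclear retained RNAs and cytosolic ribosomal protein genes were -0.454 and -0.62. The 3 measured mitochondrially encoded loci, with MT-ND1/MT-ND2 at 2.45, had a median of 3.65 (camera with Benjamini-Hochberg adjustment, adjusted p = 3.15e-05, adjusted p = 0.116 with an estimated correlation).

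Other lists did not pass in RISC enrichment with the control oligo. PARP and base excision repair genes had 11 higher and 4 lower of 28 (adjusted p = 0.354), and apoptosis genes 12 and 1 of 33 (adjusted p = 0.205, both camera with Benjamini-Hochberg adjustment). The interferon response genes had 2 and 1 of 29 (adjusted p = 0.369), epithelial markers 4 and 0 of 8 (adjusted p = 0.354) and haematopoietic markers 1 and 0 of 4 (adjusted p = 0.596, all camera with Benjamini-Hochberg adjustment). The medians of AGO and RISC factors (0.05, 5 higher and 2 lower of 14), mitochondrial dynamics (0.19, 11 and 3 of 29), hypoxia response (0.13, 9 and 1 of 31) and replication dependent histones (0.09, 2 and 0 of 22) turned negative under median-ratio scaling (-0.14, -0.01, -0.06 and -0.08). Of the 2 fibroblast and endothelial marker loci, 1 was higher.

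With either mimic MT-ND6, MT-CYB and the mitochondrial pseudogenes MTND1P23 and MTND2P28 again stood highest in RISC RNA. With miR-668, MT-ND6 (3.95), MTND1P23 (3.54), MT-CYB (3.53), MTND2P28 (3.37) and ZYX (2.88) led, and ASMTL-AS1 (-3.73), NCRNA00106 (-2.91), GOLGA8A/GOLGA8B (-2.90), RAB11FIP3 (-2.85) and MST1 (-2.53) were lowest. Mean FPKM in RISC RNA with miR-668 was under 1 for ASMTL-AS1 (0.171), NCRNA00106 (0.389) and RAB11FIP3 (0.290), so their order depends on the added 1 FPKM. With miR-489, MTND1P23 (4.36), MTND2P28 (4.08), MT-ND6 (4.03), MT-CYB (3.84) and ZNF385A (3.04) led, and ASMTL-AS1 (-3.07), GOLGA8A/GOLGA8B (-2.80), RAB11FIP3 (-2.79), PPP2R3B-AS1 (-2.36) and the pseudogene SNX18P3 (-2.31) were lowest. MTFP1/SEC14L2 rose 0.81 in RISC RNA over total RNA with miR-668 (SE 0.145, limma with Benjamini-Hochberg adjustment, adjusted p = 0.000246) and not with miR-489 (-0.20, adjusted p = 0.286). PARP1 rose 0.39 with miR-668 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0297) and not with miR-489 (0.06, adjusted p = 0.761). The PARP1 contrast was 0.15 under median-ratio scaling and 0.14 after length and GC correction (limma adjusted p = 0.393 and 0.368). It was not past the threshold under quantile scaling (0.0512), with loci of low values kept (0.0674) or without miR668_total I, miR668_total II, miR668_RISC I or miR668_RISC III (limma adjusted p from 0.0709 to 0.138). AGO2 rose 2.27 and 2.48 with miR-668 and miR-489 (limma with Benjamini-Hochberg adjustment, adjusted p = 3.77e-06 and 2.02e-06). Counts by limma were 4506 higher and 2180 lower with miR-668 (67.4% higher, against 43.6% under median-ratio scaling with 2753 and 3557 and a median shift of -0.193, and 52.3% after length and GC correction of 11210 loci, from 72.6% before it, with a shift of -0.181). With miR-489 they were 4103 and 2161 (65.5% higher, against 44.6% under median-ratio scaling with 2651 and 3295 and a shift of -0.158, and 51.4% after length and GC correction of 11210 loci, from 71.3% before it, with a shift of -0.166). As with the control oligo, the corrected splits also reflect the same mean given to all libraries. Of the loci higher with the control oligo, 3250 were also higher with miR-668 (1210 expected from independent draws) and 3299 with miR-489 (1110 expected). Across all loci the Pearson correlation of the enrichments was 0.734 for control and miR-668, 0.753 for control and miR-489 and 0.649 for both mimics.

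The joint locus MTFP1/SEC14L2 passed the threshold for recruitment with miR-668, but not when certain single libraries were left out. Its FPKM was 22.2 ± 3.93 in total and 20.2 ± 2.61 in RISC RNA with the control oligo, and 25.5 ± 2.35 and 46.2 ± 9.46 with miR-668 (SD, n = 3). The most recruited transcripts with miR-668 were those of C9orf85, an uncharacterised gene, RPL36, which encodes a cytosolic ribosomal protein, EEF1G, a subunit of translation elongation factor 1 that shares a locus with the uridylyltransferase TUT1, and C19orf52, a component of the mitochondrial import machinery. They were joined by TST, the mitochondrial sulfurtransferase rhodanese, the methyltransferase SMYD3, ATP6AP2, an accessory protein of the vacuolar proton pump, TMEM160, and B9D2 of the ciliary transition zone. PPFIBP1, a liprin of cell adhesion sites, CLASP1, which stabilises microtubules, and the signalling genes SOCS6 and RRAS2 moved the other way.

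Recruitment of MTFP1/SEC14L2 with miR-668 was 0.93 (SE 0.205, 95% confidence interval 0.499 to 1.37, limma with Benjamini-Hochberg adjustment, adjusted p = 0.025). It was not past the threshold without NC_total II, NC_total III, NC_RISC I, NC_RISC II, miR668_total I, miR668_total III or miR668_RISC II (adjusted p from 0.0502 to 0.0817, contrast from 0.78 to 0.97), with loci of low values kept (0.0674) or without the 6 libraries of repeat II (0.72, adjusted p = 0.341). Under the other settings and omissions its limma adjusted p was 0.0109 to 0.0462. The locus joins both genes over chr22 30279144 to 31530682 (GRCh37), so the change cannot be assigned to MTFP1 alone, and no miR-668 site was found in MTFP1, whose 3' UTR holds a miR-489 7mer. PARP1 was not recruited by miR-668 (0.23, adjusted p = 0.705), nor was AGO2 (-0.27, adjusted p = 0.846, both limma with Benjamini-Hochberg adjustment). C9orf85 rose 2.47 (SE 0.411, adjusted p = 0.00379), RPL36 2.04 (SE 0.135, adjusted p = 5.06e-07), EEF1G/TUT1 1.76 (SE 0.0958, adjusted p = 5.38e-08), C19orf52 1.71 (adjusted p = 9.43e-06) and TST 1.63 (adjusted p = 0.000146, all limma with Benjamini-Hochberg adjustment). SMYD3 rose 1.59 (adjusted p = 0.0152), ATP6AP2 1.57 (adjusted p = 2.49e-05), TMEM160 1.53 (adjusted p = 0.00749) and B9D2 1.53 (adjusted p = 0.0492, all limma with Benjamini-Hochberg adjustment). RPL36 changed from 1774 ± 73.4 in total and 1165 ± 32.5 in RISC RNA with the control oligo to 1248 ± 93.5 and 3378 ± 337 with miR-668 (SD, n = 3). EEF1G/TUT1 went from 955.9 ± 9.34 and 885.7 ± 33.7 to 467.5 ± 30.0 and 1468 ± 47.9, and ATP6AP2 from 53.4 ± 4.12 and 42.3 ± 3.69 to 24.9 ± 0.619 and 60.4 ± 4.68 (SD, n = 3). PPFIBP1 (-1.3, SE 0.243), CLASP1 (-0.99), SOCS6 (-0.98), RRAS2 (-0.88), LZIC (-0.80), ZDHHC17 (-0.79), RANBP9 (-0.59) and LMAN2L (-0.58) fell (limma with Benjamini-Hochberg adjustment, adjusted p from 0.00213 to 0.0464).

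Limma gave 256 loci higher and 12 lower of 15355 for recruitment with miR-668 (median SE 0.231). Of the 256, 212 were also higher in RISC RNA with miR-668 and 43 were lower in total RNA with miR-668. Recruitment is computed from both of these contrasts, so the overlaps are partly built in and were not tested. Leaving out single libraries gave 162 higher without miR668_total I, 170 without NC_total III, 7 lower without NC_total I and 31 lower without miR668_RISC I, and 48 were higher without the 6 libraries of repeat II. Sites for miR-668 lay in the 3' UTR of ATP6AP2 (8mer, chrX 40606606 to 40606613, GRCh38), C19orf52 (8mer), B9D2 and C9orf85, and in the coding sequence of EEF1G (8mer, chr11 62571013 to 62571020, GRCh38) and TMEM160. Of the 225 recruited genes with a sequence, 40 had a 3' UTR site (17.8% against 18.2% of other genes, Fisher test without matching, Benjamini-Hochberg adjusted p = 0.986), while 17 of 1948 genes without a site, matched to site genes on expression and 3' UTR length, were recruited. Recruited genes with a coding site numbered 80 (35.6% against 19.1% of other genes, Fisher test chosen after the seed tests were seen, Benjamini-Hochberg adjusted p = 1.33e-07).

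Of ribosomal protein genes RPL36 was recruited with miR-668, while RPL18 (0.41) did not pass. The list had 3 higher and 0 lower of 76, 4 and 0 when adjusted over the list alone, median 0.14, or 0.02 under quantile scaling (camera with Benjamini-Hochberg adjustment, adjusted p = 4.84e-05, adjusted p = 0.948 with an estimated correlation). Of cell cycle genes the checkpoint gene MAD2L1 (1.09), the replication helicase gene MCM5 (0.65) and CDC25B (0.61) rose and CDK1 (0.45) did not pass. They had 3 higher and 0 lower of 34, 5 and 0 when adjusted over the list alone, median 0.07, which became -0.003 under quantile scaling (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0118, adjusted p = 0.948 with an estimated correlation). ER chaperones, with CRELD2 at 0.82, HSPA5 at 0.77, SDF2L1 at 0.69 and HERPUD1 at 0.47, had no member past the threshold of 22 and a median of 0.33 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.015, adjusted p = 0.948 with an estimated correlation). Of mitochondrial dynamics genes STOML2 (0.86) and the joint locus MTFP1/SEC14L2 rose and BNIP3 (0.73) and OPA1 (-0.49) did not pass. This list, with 2 higher of 29, or 3 when adjusted over the list alone, was not called (camera with Benjamini-Hochberg adjustment, adjusted p = 0.647), its median of 0.05 turning to -0.02 under quantile scaling. Of the 2 study target loci, MTFP1/SEC14L2 was the 1 higher. RAN (0.74), the GTPase of nuclear transport, was the 1 higher of 14 AGO and RISC factors, LSM1 (0.81) of the decay genes, CDC34 (0.56) of the let-7 targets and KRT19 (1.12) of the epithelial markers, and none of these lists was called by camera.

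In RISC RNA with miR-668, without subtraction of total RNA, C10orf125, a fucose metabolism gene, RPL36, the mesoderm factor MESP1, C9orf89 and the DNA repair gene MGMT stood highest over the control oligo. PIP5KL1, ARL15, NKAIN2, OLFML2B and the planar polarity gene PRICKLE1 stood lowest. MTFP1/SEC14L2 rose 1.14 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.000191), and PARP1 (0.21) did not pass. C10orf125 rose 1.55, RPL36 1.53, MESP1 1.48, C9orf89 1.43 and MGMT 1.38 (limma with Benjamini-Hochberg adjustment, adjusted p from 3.47e-07 to 0.0486). PIP5KL1 (-1.04), ARL15 (-0.96), NKAIN2 (-0.95), OLFML2B (-0.95) and PRICKLE1 (-0.94) fell (limma with Benjamini-Hochberg adjustment, adjusted p from 0.0196 to 0.0462). There were 657 higher and 177 lower loci by limma. Without NC_RISC I these were 410 and 112, without NC_RISC II 376 and 61, and without miR668_RISC II 403 and 47, and 99 were lower without NC_RISC III.

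Several lists were called in RISC RNA with miR-668. Ribosomal protein genes (RPL36, RPL18 at 0.56) had 8 higher and 0 lower of 76, and 8 when adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 3.48e-09, adjusted p = 0.703 with an estimated correlation). Their median of 0.18 was 0.04 under quantile scaling, and the contrast correlated with log transcript length over 11210 loci (r = -0.339). Among epithelial markers KRT19 (1.13) and EPCAM (0.54) rose, 2 of 8, or 3 when adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.000605, adjusted p = 0.607 with an estimated correlation). Cell cycle genes had 8 higher and 1 lower of 34, 10 and 1 when adjusted over the list alone, with MAD2L1 (1.12), CDC25B (0.61) and MCM5 (0.60) up and CCND1 (-0.75) down (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00175, adjusted p = 0.607 with an estimated correlation). The p53 targets CDKN1A, in a locus with SRSF3 (0.70), and BAX (0.64) rose while FDXR (0.68) did not pass, with 3 higher of 25, or 4 when adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00404, adjusted p = 0.607 with an estimated correlation). The let-7 targets had 1 higher and 2 lower of 27, 1 and 3 when adjusted over the list alone, with CDC34 (0.67) up, CCND1 down and DICER1 (-0.60) and HMGA2 (-0.57) not past the threshold (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00524, adjusted p = 0.607 with an estimated correlation). The hypoxia genes BNIP3 (0.88), ALDOA (0.51) and PGK1 (0.48) rose and NDRG1 (0.45) did not pass, with 4 higher of 31 and 4 when adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0133, adjusted p = 0.607 with an estimated correlation).

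In total RNA with miR-668, C9orf85, ATP6AP2 and EEF1G/TUT1 were among the loci that fell most, with GOLM1, a Golgi membrane protein gene, VPS4A, an ATPase of the ESCRT pathway, ARL6IP1, which shapes ER membranes, and PRDX3, a mitochondrial peroxiredoxin. The nuclear RNA MALAT1, ELAVL2, which encodes a neuronal RNA-binding protein, the Ras-related gene RRAS2 and YTHDF2, a reader of methylated adenosine in mRNA, rose. MTFP1/SEC14L2 (0.21, adjusted p = 0.704) and PARP1 (-0.02, adjusted p = 0.988, both limma with Benjamini-Hochberg adjustment) did not change.

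GOLM1 fell by 1.12 (SE 0.0879, adjusted p = 6.8e-06), from 61.6 ± 3.09 to 27.9 ± 1.37 FPKM while it stood at 65.1 ± 4.86 and 65.1 ± 7.73 in RISC RNA (SD, n = 3), ATP6AP2 fell by 1.07 (adjusted p = 0.00011) and EEF1G/TUT1 fell by 1.03 (SE 0.0677, adjusted p = 9.23e-07, all limma with Benjamini-Hochberg adjustment). C9orf85 (-1.33), VPS4A (-0.95), ARL6IP1 (-0.94), AKAP2/PALM2/PALM2-AKAP2 (-0.89), BCL7B (-0.87), PRDX3 (-0.87) and UFSP2 (-0.83) fell (limma with Benjamini-Hochberg adjustment, adjusted p from 6.1e-05 to 0.0475). VPS4A carries a miR-668 8mer in its 3' UTR (chr16 69324828 to 69324835, GRCh38). MALAT1 rose 0.89, ELAVL2 0.86, RRAS2 0.82, SLC9A3 0.80, SFMBT1 0.78, FCHSD2 0.76, ZNF711 0.65, NAE1 0.62, NSF 0.61 and YTHDF2 0.61 (limma with Benjamini-Hochberg adjustment, adjusted p from 0.00351 to 0.0475). Of the 9 risen genes named here that have a gene model, 8 carry a 3' UTR match of the control word, with 8mers in RRAS2, SFMBT1, NSF and YTHDF2, so a change in the control cells is not separated from one with the mimic. There were 42 higher and 78 lower loci by limma, with 6 to 22 higher and 20 to 62 lower when any 1 of the 6 libraries was left out. Of 68 lower genes with a sequence, 34 had a miR-668 site in the 3' UTR (50% against 18% of other genes, Fisher test chosen after the seed tests were seen, Benjamini-Hochberg adjusted p = 4.37e-08). Of the p53 targets PHLDA3 (0.48), AEN (0.39), FDXR (0.38) and BAX (0.37) stood highest, with 0 of 25 past the threshold in limma (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00206, adjusted p = 0.773 with an estimated correlation). Among epithelial markers EPCAM (0.52), JUP/KRT17 (0.30), KRT8 (0.25) and KRT18 (0.07) had 0 of 8 past the threshold and 1 when adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00781, adjusted p = 0.764 with an estimated correlation). The ER chaperones HSPA5 (-0.61), SEL1L (-0.33), HYOU1 (-0.31) and PDIA4 (-0.29) stood lower, 0 of 22 past the threshold in limma (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0245, adjusted p = 0.902 with an estimated correlation).

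PARP1 was not recruited to RISC by miR-489. Its FPKM was 163.8 ± 12.7 in total and 183.4 ± 20.1 in RISC RNA with the control oligo, and 188.5 ± 14.4 and 196.3 ± 5.72 with miR-489 (SD, n = 3). In all 5 loci were recruited by miR-489: MDH1, the cytosolic malate dehydrogenase, CDIPT, which makes phosphatidylinositol, SON, a splicing cofactor, the non-coding NCRNA00205 and a locus that joins the N-terminal acetyltransferase gene NAA10 with ARHGAP4, L1CAM and RENBP. All 5 also fell in total RNA with miR-489, a contrast that recruitment subtracts, so this overlap is partly built in. CDIPT had FPKM of 27.6 ± 0.884 in control RISC RNA and 28.0 ± 2.58 with miR-489, against 28.5 ± 1.66 and 15.7 ± 1.68 in total RNA (SD, n = 3).

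Recruitment of PARP1 with miR-489 was -0.10 (SE 0.194, 95% confidence interval -0.51 to 0.314, limma with Benjamini-Hochberg adjustment, adjusted p = 0.973). A miR-489 8mer lies in its coding sequence (chr1 226367508 to 226367515, GRCh38) a miR-668 8mer lies there too (chr1 226402215 to 226402222, GRCh38), and no miR-489 site was found in its 3' UTR. MTFP1/SEC14L2 (-0.08, adjusted p = 0.98) and AGO2 (-0.07, adjusted p = 0.994) did not change either (both limma with Benjamini-Hochberg adjustment). ARHGAP4/L1CAM/NAA10/RENBP rose 0.92 (SE 0.129, adjusted p = 0.0177), NCRNA00205 0.87 (adjusted p = 0.0432), MDH1 0.84 (SE 0.116, adjusted p = 0.0177), CDIPT 0.84 (adjusted p = 0.0206) and SON 0.76 (adjusted p = 0.0432, all limma with Benjamini-Hochberg adjustment). MDH1 went from 88.3 ± 1.54 and 86.3 ± 6.47 FPKM in total and RISC RNA to 62.8 ± 4.45 and 110.9 ± 9.51 (SD, n = 3). Sites for miR-489 lie in the coding sequence of MDH1 (8mer, chr2 63604777 to 63604784) and NAA10 (8mer, chrX 153930021 to 153930028), in the 3' UTR of CDIPT (chr16 29858520 to 29858526, all GRCh38) and at 8 coding positions and 1 3' UTR position of SON. Limma called 5 higher and 0 lower of 15355, against 491 higher and 426 lower before adjustment, and none was left without NC_total II, NC_total III or NC_RISC II, while 8 were higher without miR489_total I. Without NC_total I or miR489_RISC II 1 was left, without NC_RISC I or miR489_total II 2, and without miR489_total III or miR489_RISC I 3. No list was called by camera in the fit without the repeat number: of PARP and base excision repair genes MUTYH (-0.42), APTX (-0.42), NEIL3 (-0.28) and LIG1 (-0.27) were lowest (camera with Benjamini-Hochberg adjustment, adjusted p = 0.314). Of AGO and RISC factors TNRC6A (-0.57), TNRC6C (-0.57), TNRC6B (-0.43) and DICER1 (-0.33) did not pass (camera with Benjamini-Hochberg adjustment, adjusted p = 0.128).

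In RISC RNA with miR-489 the histone gene HIST1H2BC, the epidermal gene CNFN, LRRC28 and the corepressor gene SAP30L stood highest, and OAZ3, an antizyme that controls polyamines, the lipoxygenase gene ALOX5, MMEL1 and the ankyrin gene ANK2 lowest. HIST1H2BC rose 1.55, CNFN 1.19, LRRC28 1.0 and SAP30L 0.85 (limma with Benjamini-Hochberg adjustment, adjusted p from 0.0388 to 0.0439). NCRNA00106 was listed at 0 in all 3 control libraries and C8G in all 3 miR-489 libraries, so no fold is given for them. OAZ3 fell by 2.02, from 15.6 ± 4.99 to 3.15 ± 1.48 FPKM (SD, n = 3), and ALOX5 (-1.32), MMEL1 (-1.3) and ANK2 (-0.98) fell (limma with Benjamini-Hochberg adjustment, adjusted p from 0.0388 to 0.0447). PARP1 (0.10, adjusted p = 0.804) and MTFP1/SEC14L2 (0.09, adjusted p = 0.859, both limma with Benjamini-Hochberg adjustment) did not change. Limma called 47 higher and 36 lower (56.6% higher), 32 and 75 under median-ratio scaling (29.9%), 46 and 97 under quantile scaling (32.2%) and, among 11210 loci, 52 and 53 before length and GC correction (49.5%) and 69 and 87 after it (44.2%). The length and GC correction also gave all libraries the same mean over these loci. When any 1 of the 6 libraries was left out 0 to 32 were higher and 0 to 17 lower. The hypoxia genes SLC2A3 (0.67), BNIP3 (0.57), P4HA1 (0.51) and LDHA (0.45) stood higher with 0 of 31 past the threshold in limma and 1 when adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0383, adjusted p = 0.663 with an estimated correlation). The cell cycle genes TYMS (0.49), AURKA (0.37), CCND3 (0.35) and RRM1 (0.31) had 0 of 34 past the threshold and 5 when adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0383, adjusted p = 0.663 with an estimated correlation).

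In total RNA with miR-489, LAPTM4B, a lysosomal membrane protein gene, MRPL24 of the mitochondrial ribosome, CMTM6, which stabilises PD-L1, and MRC2, a collagen receptor gene, were among the loci that fell most. ELAVL2, the cytokine gene LIF, the kinase gene HIPK1, the decoy death receptor gene TNFRSF10D, the histone gene HIST1H2BK and UGCG, which makes glucosylceramide, rose. PARP1 (0.20, adjusted p = 0.522) and MTFP1/SEC14L2 (0.17, adjusted p = 0.622, both limma with Benjamini-Hochberg adjustment) did not change.

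MRPL24 fell by 0.95 (SE 0.0901, adjusted p = 0.000202), LAPTM4B fell by 0.99 (adjusted p = 0.00222) and CMTM6 fell by 0.89 (adjusted p = 0.00222, all limma with Benjamini-Hochberg adjustment). C9orf85 (-1.17), PCOLCE2 (-1.06), HSD17B8 (-1.04), SEMA4G (-1.0), PAQR6 (-0.96), C8orf73/NAPRT1 (-0.91) and MRC2 (-0.90) fell (limma with Benjamini-Hochberg adjustment, adjusted p from 0.00426 to 0.0484). CMTM6 (chr3 32483250 to 32483257, GRCh38) and PCOLCE2 (chr3 142817998 to 142818005, GRCh38) carry miR-489 8mers in the 3' UTR. ELAVL2 rose 1.10 (SE 0.19, adjusted p = 0.00718), LIF 0.95, ASMTL-AS1 0.93, ARAP2 0.87, HIPK1 0.86, C9orf3 0.82, TNFRSF10D 0.82, HIST1H2BK 0.81, UGCG 0.80 and GOLGA4 0.80 (limma with Benjamini-Hochberg adjustment, adjusted p from 0.00217 to 0.0472). ELAVL2, LIF, ARAP2, HIPK1 and UGCG carry a 3' UTR match of the control word. Limma called 167 higher and 179 lower (48.3% higher), against 113 and 297 under median-ratio scaling (27.6%) and 150 and 267 under quantile scaling (36.0%). When any 1 of the 6 libraries was left out 30 to 63 were higher and 42 to 98 lower. Of 161 lower genes with a sequence 47 had a miR-489 3' UTR site (29.2% against 19.9%, Fisher test chosen after the seed tests were seen, Benjamini-Hochberg adjusted p = 0.015).

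The histone genes HIST1H2BK and HIST1H2BD (0.70) rose in total RNA with miR-489, while HIST1H2AI/HIST1H3H (0.75) and HIST1H2AC (0.40) did not pass. The histone list had 2 higher of 22, 5 when adjusted over the list alone, median 0.34 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00487, adjusted p = 0.125 with an estimated correlation), and histone copies share reads. The interferon genes IFIT1 (-1.48, SE 0.912), OAS1 (-1.28), BST2 (-1.23) and IFIT3 (-1.14) stood lower with 0 of 29 past the threshold, and 0 before adjustment, in limma without the repeat number, median -0.70 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00487, adjusted p = 0.72 with an estimated correlation). These genes were highest in repeat II in all 6 groups (mean difference 1.32, exact permutation p = 0.000643). That permutation treats the 6 groups as independent, although total and RISC RNA of the same number may come from the same cells. With the repeat number as a block in limma, 1 of the 29 was lower, 11 when adjusted over the list alone and 16 before adjustment. Of the p53 targets MDM2 (0.62) rose and TP53INP1 (0.57), RRM2B (0.55) and BTG2 (0.54) did not pass, with 1 higher of 25, or 3 when adjusted over the list alone, median 0.18 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0189, adjusted p = 0.72 with an estimated correlation). Of PARP and base excision repair genes APTX (0.40) rose while XRCC1 (-0.33), APEX2 (0.31) and FEN1 (0.26) did not pass, and the list was not called (camera with Benjamini-Hochberg adjustment, adjusted p = 0.552).

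**Figure D3:**
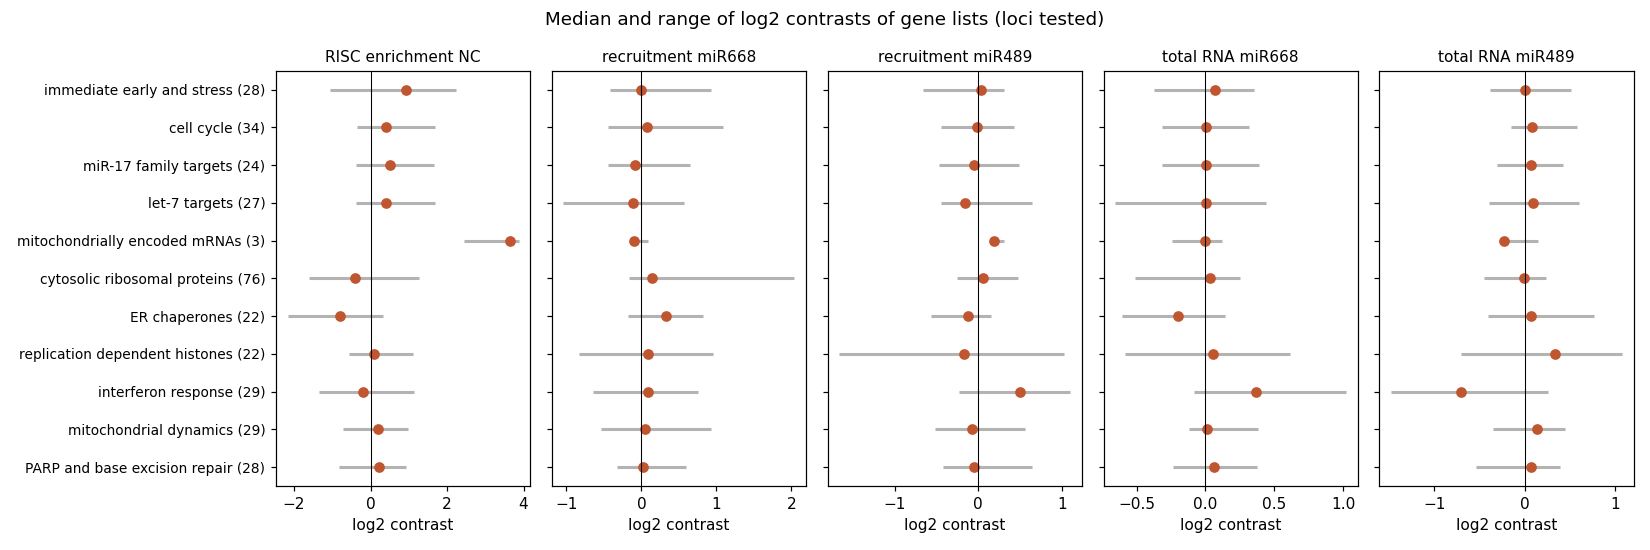
Median and range of the log2 contrasts of 11 gene lists in 5 comparisons. Dots are medians and lines run from the lowest to the highest member.

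Set directly against miR-489, miR-668 recruited RPL36, TST and ATP6AP2 more strongly. RPL36 was 1.93 higher in recruitment with miR-668, the sulfurtransferase gene TST 1.79, ATP6AP2 1.78, EEF1G/TUT1 1.71 and DPM3, a subunit of dolichol phosphate mannose synthase, 1.70 (limma with Benjamini-Hochberg adjustment, adjusted p from 8.58e-08 to 0.000261). MTFP1/SEC14L2 was 1.02 higher (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0154), and PARP1 did not differ (0.33, adjusted p = 0.535). The sulfatase gene ARSJ (-1.3), the oxysterol-binding protein gene OSBPL5 (-1.25), a locus of ZSCAN16 (-1.12), UBXN2B (-0.91) and the Wnt pathway receptor gene LGR5 (-0.83) were lower (limma with Benjamini-Hochberg adjustment, adjusted p from 0.0206 to 0.0397). The symbol ZSCAN16 also has a more abundant locus, whose values are not given here. Limma called 248 higher and 27 lower (90.2% higher). Among 11210 loci, length and GC correction took this from 251 and 24 (91.3%) to 235 and 61 (79.4%). The correction also gave all libraries the same mean, so this change is not one of length and GC content alone. Higher loci fell to 157 without miR489_total II, and lower ones to between 13 and 16 without miR668_total III, any 1 miR489_total library, miR489_RISC II or miR489_RISC III. The ER chaperones HSPA5 (1.15), SDF2L1 (0.83), PDIA4 (0.69) and MANF (0.68) stood higher with 0 of 22 past the threshold in limma, median 0.49 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.000466, adjusted p = 0.838 with an estimated correlation). MAD2L1 (1.15) and CDC25B (0.54) were the 2 higher of 34 cell cycle genes, 4 when adjusted over the list alone, and TYMS (0.48) and MCM5 (0.46) did not pass (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0487, adjusted p = 0.838 with an estimated correlation). Ribosomal protein genes, with RPL36 highest, had 2 higher of 76, and 3 higher and 1 lower when adjusted over the list alone. The median of this list, 0.09, became -0.005 under quantile scaling (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0487, adjusted p = 0.875 with an estimated correlation).

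No locus was recruited by both mimics, against 0.0834 expected from independent draws of the 256 and 5 called loci. With so few calls for miR-489 this does not show that the mimics recruit different transcripts. In total RNA 18 loci were higher and 5 lower with both mimics, against 0.457 and 0.909 expected from independent draws and 0 in simulations of noise with a shared control, and in RISC RNA 12 and 3 against 2.01 and 0.415. ELAVL2 was among those higher and C9orf85 among those lower in total RNA with both. The simulations held no effect of either mimic, and independent draws leave out the shared control. Neither gives the overlap that a shared control brings when each mimic has calls of its own. Correlations of the contrasts with each mimic were 0.29 for recruitment, 0.252 for RISC RNA and 0.301 for total RNA, below the 0.50, 0.494 and 0.502 of the simulations without a mimic effect.

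Genes with a seed match of the transfected mimic stood slightly lower in total RNA and slightly higher in recruitment, without passing the threshold over all sites. Recruitment subtracts total RNA, so these are not separate results. The miR-668 word GAGTGAC ranked first of all 7-base 3' UTR words for recruitment with miR-668 (z 10.58) and last for total RNA with miR-668 (z -11.51). The miR-489 word GATGTCA ranked first for recruitment with miR-489 (z 7.71) and last for total RNA with miR-489 (z -13.78). In RISC RNA itself GATGTCA ranked last with miR-489 (z -5.25), and GAGTGAC ranked 58 with miR-668 (z 3.31), behind the control word GGTTGTG at 19 (z 3.70). These ranks were taken without matched genes, after regression on expression and on length and GC content of the 3' UTR and coding sequence. Their z treats genes as independent, and they were computed after the seed tests.

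For miR-668, 1948 of 2020 genes with a 3' UTR site could be matched. They differed from matched genes by 0.059 in recruitment (camera with Benjamini-Hochberg adjustment, adjusted p = 0.079) and -0.053 in total RNA (adjusted p = 0.0597). For miR-489, 2118 of 2219 genes were matched and differed by 0.042 in recruitment (adjusted p = 0.155) and -0.053 in total RNA (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0597). With the estimated correlation the adjusted p was 0.972 in all 4, and 11, 23, 0 and 16 of 100 draws of matched genes passed. In RISC RNA the same genes differed by only 0.0137 for miR-668 and -0.00763 for miR-489 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.932 and 0.9). Recruitment subtracts total RNA, so its differences over all sites came mainly from the fall in total RNA. They do not show a gain in RISC RNA. An earlier and smaller match of gene names put the miR-668 total RNA difference at -0.059 with adjusted p = 0.00906 (camera with Benjamini-Hochberg adjustment, unadjusted p = 0.125 with an estimated correlation). Matching on expression alone, without 3' UTR length, gave 0.00727 and -0.0558 for miR-668 and 0.0119 and -0.00403 for miR-489. Genes with an 8mer site differed from matched genes by 0.148 in recruitment and -0.066 in total RNA for miR-668 and by 0.144 and -0.103 for miR-489 (358 and 289 genes, camera with Benjamini-Hochberg adjustment, adjusted p from 0.000158 to 0.00111, unadjusted p from 0.0512 to 0.101 with an estimated correlation). Sites of the other mimic did not separate: miR-668 sites differed by -0.012 in recruitment and -0.004 in total RNA with miR-489, and miR-489 sites by -0.028 and 0.005 with miR-668 (camera with Benjamini-Hochberg adjustment, adjusted p from 0.9 to 0.933). The score of miR-668 sites was lower in all 3 total RNA libraries with miR-668 than in the 3 control libraries (mean difference -0.057), as was that of miR-489 sites with miR-489 (-0.059, exact permutation p = 0.1 in both, the smallest possible with 3 and 3).

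**Figure D4:**
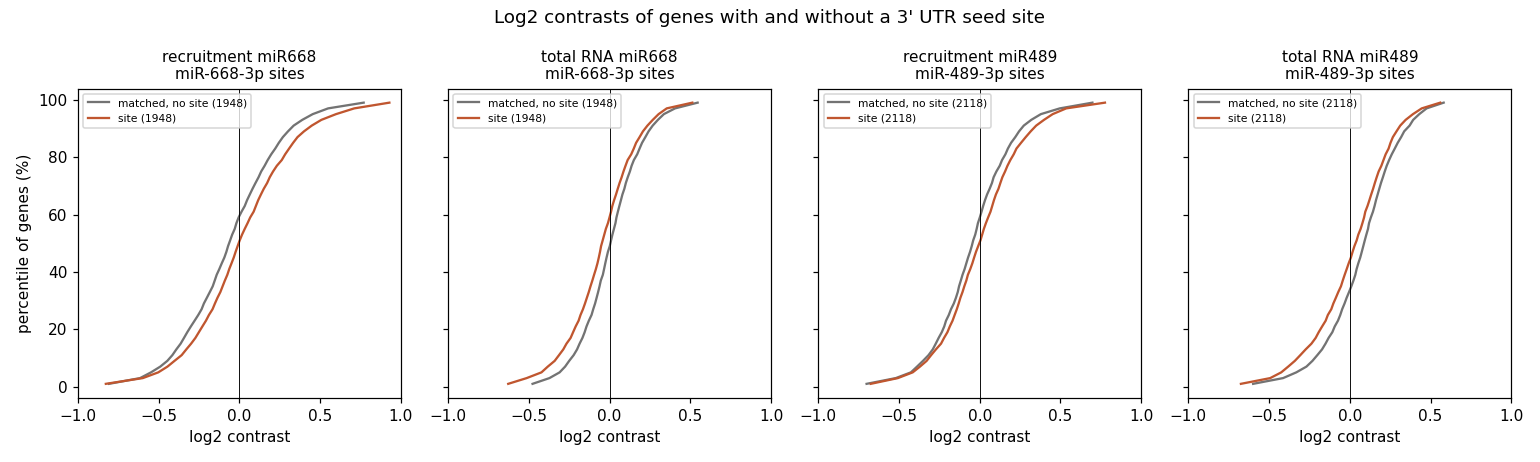
Cumulative distribution of log2 contrasts of genes with a 3' UTR seed match and matched genes without one. Panels show recruitment and total RNA with each mimic.

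**Figure D5:**
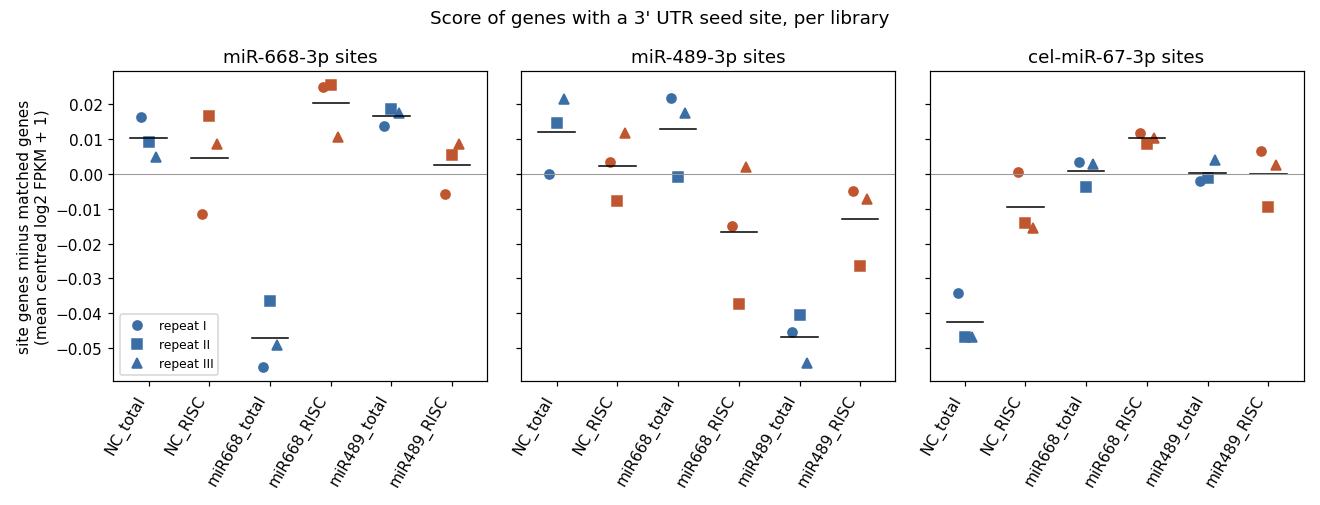
Score of genes with a 3' UTR site minus matched genes in each library for the miR-668, miR-489 and control words. Lines are group means.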

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

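The splits of the libraries given here were counted only after the results they bear on had been seen, while the comparison of both mimics was fixed from the start. A limma contrast of miR-668 recruitment minus miR-489 recruitment tested the difference itself, and 248 loci were recruited more strongly and 27 less strongly with miR-668 (Benjamini-Hochberg adjusted p at most 0.05). RPL36 (1.93), TST (1.79), ATP6AP2 (1.78), EEF1G/TUT1 (1.71) and DPM3 (1.7) had the largest positive differences, and MTFP1/SEC14L2 (1.02), the locus of a gene the study followed up, passed as well. The differences of ARSJ (-1.3), OSBPL5 (-1.25), ZSCAN16 (-1.12), UBXN2B (-0.91) and LGR5 (-0.83) were the largest negative ones among named loci. The control oligo cancels from the estimate of this contrast, while its 6 libraries still enter the residual variance. No test for outlying values within groups of 3 was made, and the omission of single libraries is given under the processing choices.

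In 100 splits drawn with a fixed seed, only the real grouping (1 of 100) called as many loci for the difference between both mimics (275, highest other 120). These splits did not keep libraries of the same repeat number together. They regrouped the RISC and total RNA libraries separately, so some could keep the real grouping of 1 fraction and with it a mimic effect. Their counts are therefore no measure of chance alone. For recruitment with miR-668 only the real grouping reached its count as well (1 of 100, 268 loci, highest other 198), where the closest other split called most of the real count. For recruitment with miR-489, 3 of 100 splits called as many loci as the real grouping, and 1 other split called 29 against the real 5. Which libraries that split grouped was not examined, so a random grouping is not excluded here. The 5 loci MDH1, CDIPT, SON, NCRNA00205 and ARHGAP4/L1CAM/NAA10/RENBP rest on a weak contrast. The remaining comparisons set 3 libraries against 3 and have 10 splits each, too few for a share under 0.05, and in each only the real grouping (1 of 10) reached its own count. The real counts and the highest of the other splits were 6275 and 1 for RISC enrichment with the control oligo, 6686 and 1 with miR-668 and 6264 and 1 with miR-489. They were 834 and 3 for RISC RNA with miR-668, 83 and 2 for RISC RNA with miR-489, 120 and 7 for total RNA with miR-668 and 346 and 1 for total RNA with miR-489.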

How the results depend on the processing

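The omission of all libraries of repeat II, the length and GC correction, the removal of small RNA loci and of loci without a symbol, the coding sites, the GC matching, the control seed, the use of the first name table alone and the block for the interferon list were chosen only after the data had been seen. Of 2803 values of named genes across all settings, 2338 kept their direction and their side of the threshold, 464 kept the direction but were no longer past it, 1 came past it and 0 changed direction beyond it. MTFP1/SEC14L2 in RISC enrichment with miR-489 was the one that came past it (-0.39 under median-ratio scaling, limma with Benjamini-Hochberg adjustment, adjusted p = 0.0455). A restriction to loci with an accepted estimate was not run, because the table holds no such column. The cause was not tested for the shifts below except where observations give a test.

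With a pseudocount of 0.1, RISC RNA with miR-489 had 55 lower loci rather than 36. With a pseudocount of 5 no count moved by over 1.5 times. With no filter on low values, recruitment with miR-489 had 5 lower, RISC RNA with miR-668 about 1.1e+02 lower and RISC RNA with miR-489 20 higher and 22 lower. With FPKM of at least 5, RISC RNA with miR-489 had 71 higher and 65 lower, and the called lists fell to 0 for RISC RNA with miR-489, 1 for total RNA with miR-668 and 1 for the difference between mimics. Under median-ratio scaling RISC enrichment had 2667 higher and 3264 lower with the control oligo, 2753 and 3557 with miR-668 and 2651 and 3295 with miR-489, RISC RNA with miR-489 had 75 lower and total RNA with miR-489 297 lower. Under quantile scaling within each fraction RISC RNA with miR-489 had 97 lower. With repeats as a block, recruitment with miR-489 had 8 higher, RISC RNA with miR-489 75 higher and 57 lower and the difference between mimics 41 lower, and the block moved no other count of loci over all genes by over 1.5 times. For the interferon response list in total RNA with miR-489, the block gave 1 lower of 29 rather than 0, and 11 when adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 2.09e-10, adjusted p = 0.382 with an estimated correlation). With the block this list was also called in recruitment with miR-489 (median 0.495, adjusted p = 9.76e-05), total RNA with miR-668 (1.5e-05), RISC RNA with miR-668 (0.00216) and miR-489 (0.0328) and the difference between mimics (0.00178), where 0 of 29 loci passed in limma and 1 to 9 did before adjustment. None of these camera calls with Benjamini-Hochberg adjustment held with an estimated correlation (adjusted p from 0.641 to 0.83).

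With a 2-fold change required as well, RISC enrichment had 649 higher and 482 lower with the control oligo, 860 and 548 with miR-668 and 656 and 520 with miR-489. Recruitment had 61 and 5 with miR-668 and 0 higher with miR-489, RISC RNA 51 and 5 with miR-668 and 8 and 5 with miR-489, total RNA 0 and 6 with miR-668 and 4 and 3 with miR-489, and the difference between mimics 59 and 7. With a 1.5-fold change, RISC enrichment had 2362 and 1397, 2759 and 1425, and 2365 and 1365 in the same order, RISC RNA 281 and 65 with miR-668 and 22 and 13 with miR-489, and total RNA 13 and 31 with miR-668 and 42 and 70 with miR-489. Without the 6 libraries of repeat II, recruitment with miR-668 had 48 higher, RISC RNA 111 and 13 with miR-668 and 0 and 0 with miR-489 by limma, total RNA 4 and 12 with miR-668 and 6 and 22 with miR-489, and the difference between mimics 65 higher. The correction for length and GC content, which also set all libraries to the same mean, used 11210 rather than 15355 loci. After it RISC enrichment had 2465, 2576 and 2407 higher, recruitment with miR-668 24 lower, RISC RNA 433 higher with miR-668 and 87 lower with miR-489, and the difference between mimics 61 lower.

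With an estimated correlation between genes, 0 lists were called by camera in each comparison. For 3' UTR sites, genes with an 8mer differed by 0.148 in recruitment and -0.0658 in total RNA for miR-668 and by 0.144 and -0.103 for miR-489, past the threshold where all sites were not. With an estimated correlation these did not pass (camera, unadjusted p from 0.0512 to 0.101). Genes with at least 2 sites differed by 0.0789 and -0.062 for miR-668 and by -0.0578 in total RNA for miR-489 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0492). With FPKM of at least 5 the differences were 0.065 and -0.0571 for miR-668 and -0.0602 in total RNA for miR-489 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.0296, 0.0171 and 0.0171). No estimated correlation is given for these 2 settings. Coding sites of miR-668 gave 0.0921 and -0.0566 (adjusted p = 0.0111 and 0.0248, camera with Benjamini-Hochberg adjustment, adjusted p = 0.68 for both with an estimated correlation). The first name table alone, with 10269 genes, gave -0.0594 for miR-668 in total RNA (camera with Benjamini-Hochberg adjustment, adjusted p = 0.00906, unadjusted p = 0.125 with an estimated correlation). Matching on expression alone took the recruitment difference for miR-668 to 0.00727.

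Leaving out 1 library at a time, RISC enrichment had 3569 to 3866 higher and 1744 to 1948 lower with the control oligo, 3864 to 4498 and 1811 to 1989 with miR-668, and 3525 to 3727 and 1731 to 1910 with miR-489. Recruitment had 162 (without miR668_total I) to 274 higher and 7 (without NC_total I) to 31 lower (without miR668_RISC I) with miR-668, and 170 higher without NC_total III. With miR-489 it had 0 (without NC_total II, NC_total III or NC_RISC II) to 8 higher (without miR489_total I) and 0 to 2 lower (without miR489_total III). RISC RNA with miR-668 had 376 (without NC_RISC II) to 608 higher and 47 (without miR668_RISC II) to 263 lower, with miR-489 0 to 32 and 0 to 17. Total RNA had 6 (without NC_total I) to 22 higher and 20 (without NC_total III) to 62 lower with miR-668, and 30 (without miR489_total I) to 63 higher and 42 to 98 lower with miR-489. The difference between mimics had 157 (without miR489_total II) to 259 higher and 13 (without miR489_total I or II) to 29 lower. Each single omission moved a count of total RNA with either mimic, or of RISC RNA with miR-489, by over 1.5 times wherever the omitted library entered that comparison. Site differences ran from 0.0567 to 0.0817 and -0.0637 to -0.0457 for miR-668 in recruitment and total RNA, and from 0.033 to 0.0483 and -0.0566 to -0.0438 for miR-489.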

Other observations

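The contrasts under the control word, the mitochondrial contrasts under scaling, the length trend, the splits, the word ranks and the tests by repeat number given below were chosen only after the results had been seen. Interferon response genes, which are switched on by double-stranded RNA and other signs of infection, differed between repeat numbers more than between treatments. The mean log2 level of the 29 measured loci was 3.33, 5.12 and 3.73 in total RNA with the control oligo for repeats I, II and III, 4.17, 5.55 and 3.60 with miR-668 and 2.48, 4.18 and 3.60 with miR-489. Repeat II was highest in all 6 groups, by 1.32 on average (SD 0.241 over groups, exact permutation p = 0.000643 over 46656 permutations). RSAD2, IFIT1 and the other members therefore had wide standard errors in every comparison between treatments. The permutation and the SD treat the 6 groups as independent. Total and RISC RNA of the same number may come from the same cells, so this permutation p may be too small. AGO2 was highest in repeat I and lowest in repeat III in all 6 groups.

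ELAVL2 stood higher and C9orf85 lower in total RNA with both mimics than with the shared control. Among all 7-base words of the 3' UTR, GGTTGTG had the highest rank for total RNA with miR-668 (z 8.55) and with miR-489 (z 6.80), and was lowest for recruitment with miR-489 (z -4.03). In RISC enrichment the C-rich word CCCCCTC ranked first with the control oligo (z 8.64) and with miR-668 (z 7.40), and AU-rich words such as AAATTAG (z -4.99) ranked last with the control oligo.

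Genes whose 3' UTR holds a site of the control word, GGTTGTG or GTTGTGA, stood higher in total RNA with both mimics, or lower in the control. The test used 1920 of 1975 genes with any site, each with a matched gene (camera p = 0.0117, p = 0.273 with an estimated correlation, both unadjusted). Length and GC content of the 3' UTR are argued against as the whole cause, since the lowest of 100 draws matched on expression, length and GC kept a difference of 0.03. An aberrant control library is argued against as well: 3 of 3 control total RNA libraries had a score under all 6 mimic libraries (mean -0.0424 ± 0.0073, SD, n = 3, exact permutation p = 0.0119, the smallest possible). For 303 genes with an 8mer the difference was 0.0884 (camera p = 1.06e-06, p = 0.0118 with an estimated correlation, both unadjusted). Draws for any site gave at most 0.0456, but with 1920 pairs they do not give the spread for 303, so exceeding them is no test. Genes with an 8mer stood lower in recruitment with both mimics, which subtracts total RNA (-0.0499, camera p = 0.0236, p = 0.198 with an estimated correlation, both unadjusted). In RISC RNA genes with any site scored lower with the control oligo than with the mimics (-0.0146, exact permutation p = 0.0357). Repression by the control oligo through a cel-miR-67-like seed stays a hypothesis, found and tested on the same libraries, and the labels do not give its sequence.

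Mitochondrially encoded mRNAs such as MT-CYB and MT-ND6 stood higher in RISC RNA in all 3 treatments. Scaling of the deposited values is argued against, because the lowest of their contrasts under median-ratio scaling was 2.11 (SE 0.134). The highest median of 76 cytosolic ribosomal protein genes was -0.247 (largest SD over genes 0.664, highest member 1.45) and the lowest mitochondrial contrast 2.36. Unselective carry-over of lysate RNA would bring RISC RNA closer to total RNA for every gene, so this comparison cannot decide on it. Cytosolic mRNAs do not report on carry-over of mitochondria or their RNA, which stays open. Binding of mitochondrial RNA to the resin or to FLAG-AGO2 after lysis could also give this pattern and stays open, as no library is labelled as a pull-down without FLAG-AGO2. Whether mitochondrial transcripts enter RISC in the cell was not tested.

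The 834 loci that differed in RISC RNA with miR-668 may partly reflect transcript length. After correction for length and GC content, 59.4% of the loci called among 11210 with a gene model stayed past the threshold, 485 of 817. The median size of change of the called loci went from 0.525 to 0.441. The correction used 1 transcript per gene and set all libraries to the same mean. It can leave an effect of length behind, so it cannot decide whether length and GC content are the whole cause. A single library with a strong length trend, miR668_RISC II (r = -0.407, against -0.101 and -0.12 in the others of its group), is argued against as the whole cause, since 450 loci were called without it, yet 47 rather than 177 of them lower. Action through coding sites of miR-668 stays open: over all genes, those with a coding site differed from matched genes by 0.0317 (camera with Benjamini-Hochberg adjustment, adjusted p = 0.412), although 138 genes with a coding site against 67 matched genes were called higher and 34 against 47 lower.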
